A study of Mus musculus with 24 samples.

How the data were processed

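The series measured polyA-selected RNA from ventricular zone tissue of the embryonic mouse cortex in 24 libraries. They form 8 groups of 3, wild type (WT) and Prdm16 conditional knockout (cKO) at E11.5 and E13.5 and at E15.5 and E17.5, with the replicates lettered A, B and C. Per the labels' protocols, libraries were made with a stranded TruSeq mRNA kit and run on a HiSeq 4000. The labels speak of pairs of embryos without saying what makes a pair, whether a letter marks one, or whether a library holds 1 embryo or several. The p-values therefore measure the spread between these libraries, part of which may be technical.

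The authors deposited 1 table of 22529 genes whose signal is a normalized read count per gene and library, that is, reads divided by 1 size factor for each library. Per the submitters' processing notes, cutadapt 1.6, STAR 2.5.0a, HTSeq 0.5.3 and DESeq 1.22.1 were used with the genome build mm10 (GRCm38). The role and order of these tools, the annotation release, the treatment of reads that match several genes and the strand setting of the counting are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies may therefore share reads. The names of the WT columns at E13.5 and E17.5 carry a 2 whose meaning is not given in the sources used here.

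The deposited values are whole multiples of what 1 read is worth in each library, so whole reads could be recovered. The share of values that came out whole within 0.01 was 100%. Recovered reads ranged from 25639836 to 38879931 per library, and size factors recomputed from them were 0.997 to 1.00 times those in the deposited values. At this depth a gene at the filter's minimum of 10 rests on few reads per library, and its fold change is less certain than that of an abundant gene. Of the 22529 gene identifiers, 22411 (99.5%) matched GENCODE M21 without their version number, and coordinates are from that release on GRCm38. Among the deposited gene symbols, 25 had been turned into dates by a spreadsheet. Each was replaced by the GENCODE symbol of the same identifier, or by the identifier itself where no symbol was found. A further 13 symbols stood for 2 identifiers, which were kept apart.

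Values were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend in the prior variance. The model had 1 mean for each of the 8 groups, so that all libraries shared 1 estimate of the spread, and tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was tested if at least 3 libraries had a value of 10 or more, which left 17518 genes. Fold changes are on the log2(value + 1) scale, which understates the change of genes at low values. The comparisons were cKO minus WT on each day, their average over the 4 days, the differences between these effects (a joint F test and the differences between adjacent days), and E13.5 minus E11.5, E15.5 minus E13.5, E17.5 minus E15.5 and E17.5 minus E11.5 in WT. A set of 36 gene lists for cell types, pathways and technical checks was tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison. Members of a list were counted over all genes tested and also adjusted over the list alone.

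Genes were named by a rule. For each cKO comparison it took Prdm16, the 8 genes with the highest and the 8 with the lowest log2 fold change among those past the threshold, with a mean of at least 50 in the higher group and no overlap between libraries, and up to 3 members of each list. For the WT course it took the 6 highest, the 6 lowest and up to 3 members of each list, and for the differences between days the 8 smallest p-values. Chance alone leaves 10% of genes without overlap when 3 libraries are compared with 3. Ppargc1a and Pdzrn3 were named in every cKO comparison, and predicted genes and clone names were counted without being named. The groups, tests, gene lists, naming rule and the first set of alternatives were fixed before the data were examined. Genes named outside the rule are said to be so where they appear, and some genes that the rule names are not reported here.

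Alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, TMM factors, limma without the trend, only the 2 groups compared, the letter as a replicate block, each library left out in turn, an absolute log2 fold change of at least 1, an estimated correlation in camera and fry in place of camera. The quasi-likelihood count test of edgeR 4.0.16 on the recovered reads called 465 genes at E11.5, 4087 at E13.5, 767 at E15.5 and 7088 at E17.5. Some alternatives were added after seeing the data. They leave out 5 C libraries whose values lie near a weighted sum of A and B, or WT libraries B and C at E15.5, where Krt5 read 6658 and 3311 against 1.95 in A. Total counts of genes without the 5 C libraries are given beside the main totals, and list counts where these libraries move them by over 1.5 times.

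The test was first run on simulated reads for the 17518 genes with the real means and library sizes. In each comparison 66 or 67 genes were changed at each fold, so the shares below rest on few genes. At E11.5 it recovered 41.8% of the genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 5 unchanged genes called. At E13.5 these shares were 52.2%, 65.7% and 98.5%, with 9 unchanged genes called, and at E15.5 they were 46.3%, 82.1% and 95.5%, with 11. At E17.5 they were 53.7%, 88.1% and 98.5%, with 8, and for the average over days 92.5%, 98.5% and 100%, with 13. The fit of a library as a weighted sum was tested on simulated data for 13376 genes and returned 40.1% for a simulated share of 40%. Replicates were compared in pairs before they were averaged. The closest pair, A and C of cKO E15.5, had a median squared difference of 0.681 times counting noise and a mean of 3.05 over 13030 genes, against a median of 0.455 for counting noise alone. A library made of 2 others would differ from each of them, so comparing pairs does not show that the libraries are independent. All 24 were counted as labelled, and results without the 5 C libraries are given for that reason.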

Results

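RNA was sequenced from the ventricular zone of the embryonic mouse cortex, the layer along the ventricle in which the progenitors of cortical neurons divide. Tissue came from WT embryos and from embryos with a conditional knockout of Prdm16, a gene for a zinc-finger transcriptional regulator. Each genotype was sampled at E11.5 and E13.5, then at E15.5 and at E17.5, with 3 libraries per group, 24 in all, at 25639836 to 38879931 recovered reads per library. Values below are normalized reads with their SD (n = 3 unless stated), and fold changes are log2 with their SE and the limma adjusted p.

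**Figure D1:**
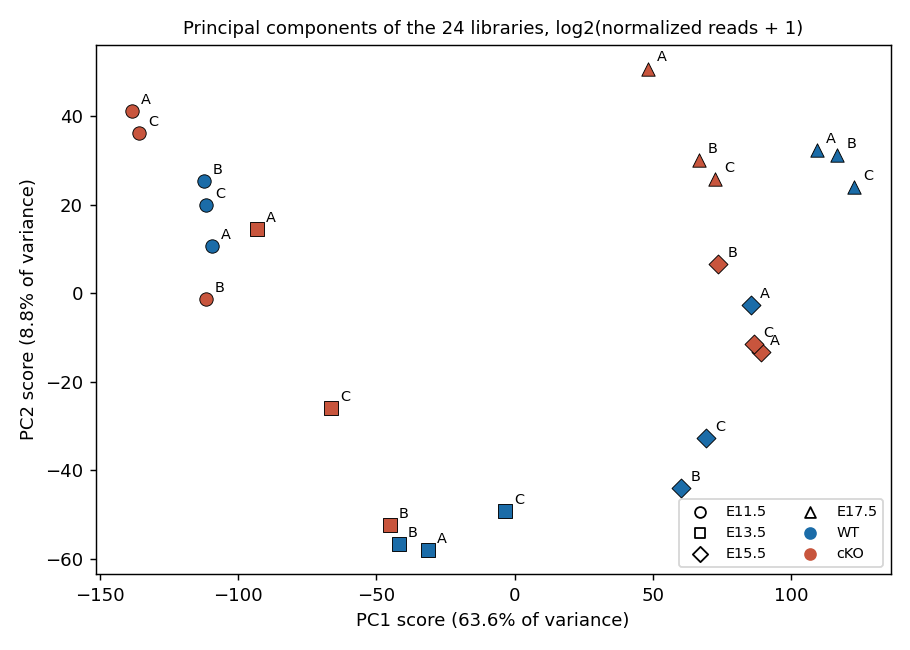
Scores of the 24 libraries on the first principal component (x axis, 63.6% of variance) and the second (y axis, 8.81%) of log2(normalized reads + 1), with a symbol for each embryonic day, a colour for each genotype and the replicate letter beside each point. The WT libraries follow one another by day along the first component, and the cKO libraries of E17.5 (48.2 to 72.5) lie below those of E15.5 (73.6 to 89.2).

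Prdm16 lies on chromosome 4 from 154316125 to 154636873 on the minus strand (GRCm38). At E11.5 it read 2206, 2030 and 2134 in the WT libraries and 868, 1397 and 873 in the cKO libraries, a log2 fold change of -1.06 ± 0.14 (adjusted p = 8.1e-05). At E13.5 it read 5329, 6369 and 4772 in WT and 1819, 1936 and 1784 in cKO (-1.56 ± 0.14, adjusted p = 1.8e-06). At E15.5 the WT libraries read 2632, 2504 and 2600 and the cKO libraries 2458, 2025 and 2345, a difference that did not pass (-0.18 ± 0.14, adjusted p = 0.88). At E17.5 Prdm16 went against the labels. The libraries labelled WT read 2070, 2000 and 2052 and those labelled cKO 2983, 3594 and 3866 (0.76 ± 0.14, adjusted p = 0.00019). Which exons were deleted is not in the labels, and reads from outside the deleted part would check nothing, so these gene totals do not test the deletion itself.

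The libraries also differed in ways that the groups do not explain. In 5 groups (WT E11.5, cKO E11.5, cKO E13.5, WT E15.5 and cKO E15.5) the values of library C could be written as A and B in shares of 31.2% and 67.9%, 87.4% and 13.5%, 43.8% and 53.4%, 49.2% and 49.5%, and 82.3% and 17.9%. The median squared residual of these fits was 0.57 to 0.906 times counting noise, where counting noise alone gives 0.455, and in the other 3 groups it was at least 1.45. Xist, which is transcribed from the inactive X chromosome, was present without Y-linked transcripts in 11 libraries, and Y-linked transcripts without Xist in 10. Library C of WT E11.5, cKO E13.5 and cKO E15.5 held both. In WT all 3 libraries were Y-linked at E13.5 and at E15.5, and all 3 held Xist without Y-linked transcripts at E17.5.

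**Figure D2:**
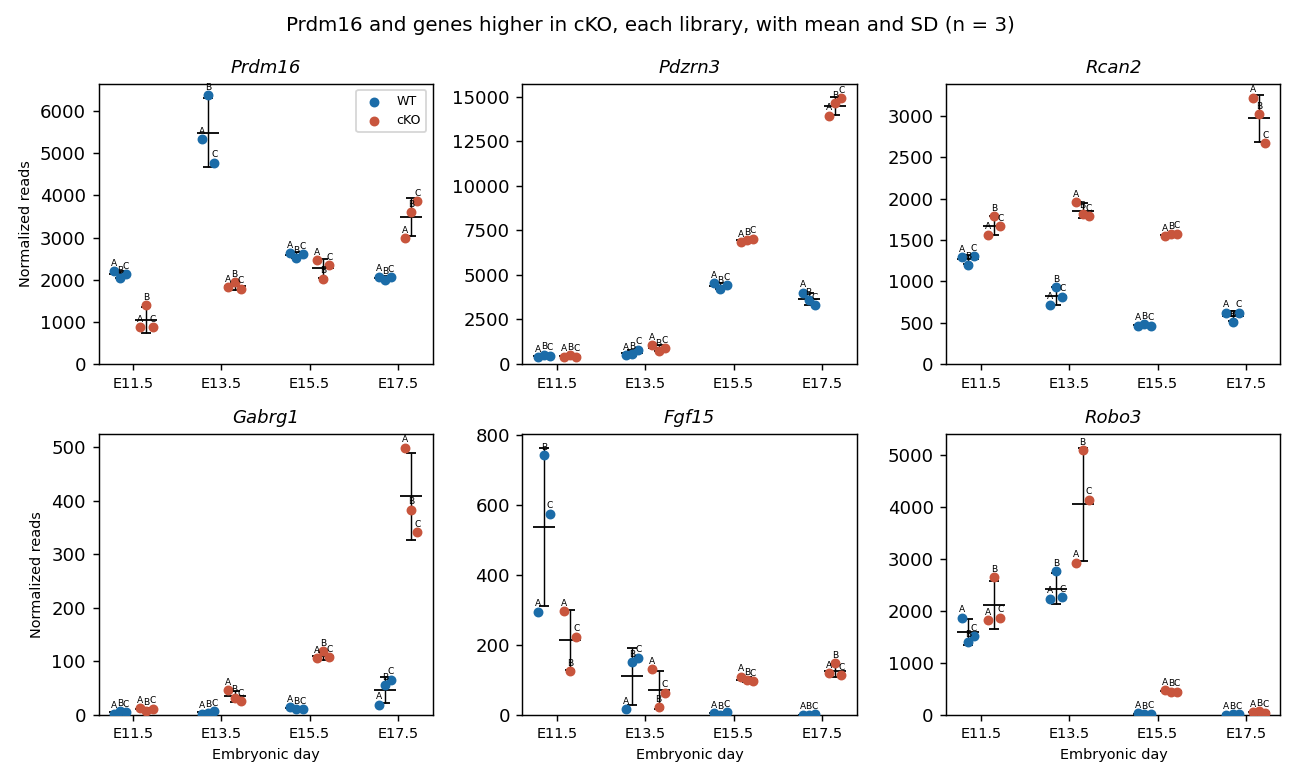
Normalized reads (y axis, linear from 0) of Prdm16, Pdzrn3, Rcan2, Gabrg1, Fgf15 and Robo3 on each embryonic day (x axis), a point for each library with the group mean and SD (n = 3), WT in blue and cKO in red. Prdm16 is lower in cKO at E11.5 and E13.5 and higher in the libraries labelled cKO at E17.5, where Pdzrn3 averages 14500 against 3630.

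At E11.5 the genes of the ventral forebrain were lower in the cKO libraries. Whether the difference comes from the genotype or from how the tissue was taken was not tested. Of 17 measured markers of ventral forebrain and interneurons, 11 fell and 6 did not pass, and 11 fell when adjusted over the list alone. Gad2, which encodes an enzyme of GABA synthesis, averaged 698 ± 48.6 in WT and 7.59 ± 4.99 in cKO (-6.53 ± 0.73, adjusted p = 1.4e-05). The homeobox genes Dlx5 and Dlx1 fell from 437 ± 44.4 to 6.64 ± 6.42 and from 2660 ± 362 to 51.2 ± 39.1. Camera gave the list an adjusted p of 1.36e-16, and the call held with an estimated correlation (adjusted p = 0.00951 with an estimated correlation). Six3 (-6.15 ± 1.21), Gsx2 (-6.06 ± 1.19) and Sp9 (-5.80 ± 0.71), also transcription factor genes, were among the 8 lowest.

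Of 10 genes on the list for the oligodendrocyte lineage, 4 fell, the same number adjusted over the list alone. Whether they fell in cells of that lineage or in the same cells as the ventral forebrain genes was not tested. Olig2 fell from 282 ± 10.5 to 19.7 ± 1.59 (-3.78 ± 0.25, adjusted p = 7.9e-09), Olig1 changed by -3.39 ± 0.50 and Lhfpl3 by -1.92 ± 0.49. For this list the camera adjusted p was 1.3e-06 (adjusted p = 0.00545 with an estimated correlation). Of 14 genes of postmitotic neurons, 6 fell (12 adjusted over the list alone), with Nefm at -1.18 ± 0.22, Mapt at -1.13 ± 0.24 and Dcx, a microtubule protein of migrating neurons, at -1.11 ± 0.19. This list had a camera adjusted p of 2.01e-09, which was lost (adjusted p = 0.308 with an estimated correlation). Limma and edgeR called 0 of these 14 genes without the 5 C libraries, and 8 were lower at an unadjusted limma p under 0.05 (camera adjusted p = 4.57e-09). Of 12 upper-layer genes, 3 fell (4 adjusted over the list alone), namely Rorb (-1.87 ± 0.24), Pou3f1 (-1.67 ± 0.23) and Pou3f2 (-1.09 ± 0.17), at a camera adjusted p of 0.00391 (adjusted p = 0.378 with an estimated correlation). The radial glia genes Ednrb (-1.08 ± 0.14), Ptprz1 (-0.81 ± 0.18) and Ddah1 (-0.72 ± 0.09) fell, 3 of 18 on that list (4 adjusted over the list alone), whose camera adjusted p was 0.0698.

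Some genes were higher in cKO at E11.5. Of 13 cortical hem genes, 2 rose (3 adjusted over the list alone), both coding for secreted enhancers of WNT signalling. Rspo2 averaged 227 ± 111 in cKO and 39.6 ± 27.7 in WT (2.58 ± 0.50, adjusted p = 0.0046), and Rspo3 rose by 1.65 ± 0.39. Camera gave the hem list an adjusted p of 0.00695 (adjusted p = 0.629 with an estimated correlation). Emx1, a dorsal telencephalic transcription factor, rose by 1.27 ± 0.30, 1 of 11 genes of area and dorsal patterning (2 adjusted over the list alone), a list with a camera adjusted p of 0.0449 (adjusted p = 0.336 with an estimated correlation). Fezf2 rose by 0.79 ± 0.15 and Mecom, which encodes a close relative of Prdm16, by 1.16 ± 0.22. Mcidas (3.23 ± 0.85), Ccno (2.73 ± 0.61) and Foxj1 (0.76 ± 0.19), regulators of multiciliated cells, made up 3 of 8 ependymal genes that rose, 3 also adjusted over the list alone, with a camera adjusted p of 0.0101 (adjusted p = 0.336 with an estimated correlation). Without the 5 C libraries limma and edgeR called 0 hem, 0 ependymal and 0 dorsal patterning genes, where 3, 3 and 2 were higher at an unadjusted limma p under 0.05. The fold changes were then 2.45 for Rspo2 (limma adjusted p = 0.25), 1.71 for Rspo3 (0.38), 3.76 for Mcidas (0.26), 2.76 for Ccno (0.29), 0.76 for Foxj1 (0.52), 1.2 for Emx1 (0.5) and 0.74 for Fezf2 (0.26), and Mecom had an adjusted p of 0.12. At the preset correlation camera still called the 3 lists, with adjusted p of 0.00665 for hem, 0.00665 for ependymal and 0.0402 for dorsal patterning genes.

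The highest fold change at E11.5 belonged to Eno1b, an intronless copy of the glycolytic enzyme gene Eno1 on chromosome 18 (48045335 to 48048412), at 3.42 ± 0.437 in WT and 3760 ± 416 in cKO (9.73 ± 0.31, adjusted p = 3.8e-14). Masp2, on chromosome 4 (148602554 to 148615499), averaged 5.28 ± 1.31 and 115 ± 28.8. Eno1b was at least 553 in each of the other 21 libraries, WT included, and its value is uncertain because reads of Eno1 can match it. Ppargc1a, a coactivator of mitochondrial genes, changed by -0.50 ± 0.13 (adjusted p = 0.038), and Pdzrn3 by -0.03 ± 0.15 (adjusted p = 0.96). Of 13 genes on the list for PGC-1 and brown fat, limma called 1 lower and edgeR 0, and both called 0 lower without the 5 C libraries.

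In all, limma called 107 genes higher and 441 lower at E11.5 (548), and 97 without the 5 C libraries, of which 96 were among the 548. At E11.5 the count was 1436 without cKO library B, 270 without WT library B, 295 without WT library C and 311 without cKO library C.

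At E13.5 single genes of WNT signalling were higher in cKO. Wnt8b, a WNT ligand of the medial cortex, averaged 583 ± 94.7 in cKO and 4.75 ± 4.72 in WT (7.20 ± 0.66, adjusted p = 1.9e-06). Rspo1 averaged 113 ± 90.8 and 6.31 ± 3.55 (3.38 ± 1.04), and the WNT targets Sp5 and Lef1 rose by 3.30 ± 0.81 and 0.92 ± 0.22. The hem list had 2 of 13 members higher, 2 also adjusted over the list alone, at a camera adjusted p of 0.06, and 1 higher without the 5 C libraries. Of 12 WNT response genes 2 rose, also adjusted over the list alone, at a camera adjusted p of 0.132. With the 5 C libraries left out, limma and edgeR called 0 WNT response genes, and 3 were higher at an unadjusted limma p under 0.05. Cyp26b1, which encodes an enzyme that degrades retinoic acid, rose from 25.2 ± 12 to 162 ± 3.48 (2.73 ± 0.60, adjusted p = 0.0046). Limma called Cyp26b1 higher on 3 of the days, and on 1 without the 5 C libraries. Mecom rose by 1.67 ± 0.22 and Dmrtb1 by 1.97 ± 0.22.

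All 12 upper-layer genes fell at E13.5, also adjusted over the list alone. Pou3f1 fell from 367 ± 110 to 89.1 ± 13.4 (-1.99 ± 0.23), Pou3f2 from 4350 ± 849 to 1280 ± 348 (-1.79 ± 0.17, adjusted p = 3.3e-06), and Inhba, at under 20 reads, changed by -2.45 ± 0.51. For the upper-layer list camera gave an adjusted p of 5.56e-10 (adjusted p = 0.0567 with an estimated correlation). Of 14 postmitotic genes 6 fell (10 adjusted over the list alone), with Dcx at -1.35 ± 0.19, Myt1l at -1.26 ± 0.24 and Mapt at -0.93 ± 0.24, at a camera adjusted p of 3.57e-05 (adjusted p = 0.606 with an estimated correlation). Among genes of neuronal migration and guidance 7 of 15 fell and 2 rose (9 and 2 adjusted over the list alone), with Robo2 at -1.50 ± 0.18, Robo1 at -1.33 ± 0.35 and Slit1 at -1.19 ± 0.35. Their camera adjusted p was 0.0047 (adjusted p = 0.606 with an estimated correlation). The intermediate progenitor genes Insm1 (-0.92 ± 0.20), Neurog2 (-0.72 ± 0.20) and Eomes (-0.41 ± 0.10) were among 4 of 12 that fell (5 adjusted over the list alone), and the list had a camera adjusted p of 0.0907. Without the 5 C libraries limma called 7 upper-layer, 2 postmitotic and 2 migration genes lower. Neither limma nor edgeR then called an intermediate progenitor gene (0 of 12, with 4 lower at an unadjusted limma p under 0.05) or a migration gene as higher (0 of 15, with 2 unadjusted). Camera at the preset correlation then gave 5.89e-10 for upper-layer, 5.91e-05 for postmitotic and 0.00465 for migration genes. Thsd4 fell from 1800 ± 392 to 156 ± 23.9 (-3.51 ± 0.23, adjusted p = 1.3e-08), and the transcription factor gene Zbtb20 by 2.37 on the log2 scale.

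Ventral forebrain genes were also lower at E13.5, with 11 of 17 past the test (13 adjusted over the list alone). Dlx2 fell from 450 ± 331 to 21 ± 4.40 (-3.84 ± 0.53), Dlx1 changed by -3.71 ± 0.75 and Gad2 by -3.68 ± 0.73. Camera gave the ventral list an adjusted p of 2.27e-06 (adjusted p = 0.375 with an estimated correlation), and 7 fell without the 5 C libraries (camera adjusted p = 3.61e-07). The WT libraries were unequal in these genes, with Dlx2 at 72.1, 687 and 591 in A, B and C. Here too, how the tissue was taken was not told apart from the genotype.

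Most genes of the mitochondrial genome and some nuclear genes of the respiratory chain were higher in cKO at E13.5. Of 8 measured genes of the mitochondrial genome, 7 rose (8 adjusted over the list alone), with mt-Nd6 at 1.23 ± 0.22, mt-Nd2 at 1.01 ± 0.16 and mt-Nd5 at 0.93 ± 0.14. Their camera adjusted p was 2.27e-06 (adjusted p = 0.415 with an estimated correlation). These genes took 1.68% to 1.96% of the reads in cKO and 0.988% to 1.13% in WT. Of 68 nuclear genes of the respiratory chain 16 rose (21 adjusted over the list alone), among them Ndufs5 (1.69 ± 0.47), Uqcrb (0.52 ± 0.14) and Ndufa5 (0.47 ± 0.16), at a camera adjusted p of 5.56e-10 (adjusted p = 0.765 with an estimated correlation). Of 40 antioxidant genes 11 rose and 1 fell (12 and 3 adjusted over the list alone), with the peroxidase genes Gpx8 at 0.80 ± 0.17, Prdx1 at 0.66 ± 0.14 and Prdx3 at 0.61 ± 0.10. Their camera adjusted p was 0.0013 (adjusted p = 0.756 with an estimated correlation). Without the 5 C libraries limma and edgeR called 3 genes of the mitochondrial genome and 1 antioxidant gene higher. They called 0 of the 68 respiratory chain genes, of which 21 were higher at an unadjusted limma p under 0.05, and 0 antioxidant genes lower, with 1 unadjusted. Camera at the preset correlation still called these lists, with adjusted p of 4.91e-06 for the mitochondrial genome, 5.89e-10 for the respiratory chain and 0.00113 for antioxidant genes. Ppargc1a fell from 515 ± 64.4 to 261 ± 13.5 (-0.97 ± 0.13, adjusted p = 0.00012), Tfam rose by 0.35 ± 0.08 and Pdzrn3 by 0.54 ± 0.15 (adjusted p = 0.016). Limma called Pdzrn3 higher on 3 of the days, and on 1 without the 5 C libraries.

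Limma called 1715 genes higher and 2196 lower at E13.5 (3911), and 138 higher and 324 lower without the 5 C libraries (462), of which 461 were among the 3911. The excess of lower genes turned with TMM factors (2021 higher and 1983 lower) and with edgeR on the recovered reads (2164 and 1923). The count was 5888 without cKO library B, 1539 without cKO A, 2300 without cKO C and 1669 without WT C.

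At E15.5 a small set of genes was higher in cKO. Robo3, a receptor that guides commissural axons, averaged 452 ± 17.5 in cKO and 17.3 ± 7.99 in WT (4.74 ± 0.32, adjusted p = 1.5e-08). The growth factor gene Fgf15 averaged 100 ± 6.57 and 3.60 ± 3.45 (4.90 ± 0.79), Gabrg1, a GABA receptor subunit, 110 ± 7.71 and 11.5 ± 1.86 (3.16 ± 0.42), and Pdlim3 99.6 ± 11.9 and 8.29 ± 2.26 (3.46 ± 0.48). Cyp26b1 (3.23 ± 0.60), Tll1 (3.10 ± 0.46), Rxrg (3.03 ± 0.62), Pdzd3 (2.77 ± 0.28), Mecom (1.35 ± 0.22) and Pdzrn3 (0.66 ± 0.15, adjusted p = 0.02) also rose. Slc14a2, a urea transporter gene, fell from 164 ± 48.7 to 8.66 ± 1.30 (-4.06 ± 0.40, adjusted p = 3.6e-06) and Dio2, which encodes a thyroid hormone deiodinase, from 156 ± 22.6 to 45.7 ± 11.6. Ppargc1a did not pass (-0.18 ± 0.13, adjusted p = 0.85).

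Of 18 radial glia genes 1 rose at E15.5 over all genes, Ednrb (0.71 ± 0.14), and 9 adjusted over the list alone, with a list median of 0.34. The camera adjusted p was 0.000157 (adjusted p = 0.342 with an estimated correlation). Both limma and edgeR called 0 of the 18 without the 5 C libraries, and 4 were higher at an unadjusted limma p under 0.05 (camera adjusted p = 3e-04). Lists of neuron genes had medians of 0.14 for 14 postmitotic genes (camera adjusted p = 0.0502), 0.27 for 12 deep-layer genes (camera adjusted p = 0.00417, adjusted p = 0.342 with an estimated correlation) and -0.31 for 12 upper-layer genes (camera adjusted p = 0.00417, adjusted p = 0.349 with an estimated correlation). Limma and edgeR called 0 genes of these lists, with 1 and 3 higher and 4 lower at an unadjusted limma p under 0.05, and the 4 upper-layer genes fell when adjusted over the list alone.

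Some of the lower genes at E15.5 followed 2 WT libraries, B and C. These may not be 2 separate samples, since the values of C could be written as 49.2% of A and 49.5% of B. Trp63, a transcription factor of epidermis, read 463 and 225 in WT libraries B and C, 1.95 in WT A and at most 0.96 in cKO (-5.76 ± 1.18, adjusted p = 0.011). Dsc3 (-5.27 ± 1.13), Col17a1 (-4.14 ± 0.77) and Col12a1 (-4.64 ± 0.74) were lower alongside it. Krt5, a keratin named after its values were seen, read 1.95, 6658 and 3311 in WT A, B and C. Of 12 genes of the meninges 3 fell (9 adjusted over the list alone), Col1a2 (-4.67 ± 1.18), Col3a1 (-4.29 ± 1.12) and Igf2 (-1.72 ± 0.44), at a camera adjusted p of 3.21e-08 (adjusted p = 0.349 with an estimated correlation). Of 12 WNT response genes 3 fell (5 fell and 1 rose adjusted over the list alone), Wif1 (-4.58 ± 1.09), Dkk1 (-3.54 ± 0.82) and Sp5 (-3.27 ± 0.81), at a camera adjusted p of 3.58e-05 (adjusted p = 0.349 with an estimated correlation). Leaving out the 5 C libraries, limma and edgeR called 0 meningeal and 0 WNT response genes, where 7 and 4 were lower at an unadjusted limma p under 0.05 (camera adjusted p = 7.27e-06 and 3e-04).

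Without WT libraries B and C the fold changes of Col1a2 and Col3a1 were 0.19 and 0.49, and those of Trp63 and Wif1 were -1.24 and -0.20. Those of Dsc3 and Col17a1 were -1.10 and -1.09, of Col12a1 -2.80, of Igf2 -0.20, of Dkk1 -1.20 and of Sp5 -0.71, and limma called none of these 10. Robo3 (4.16), Cyp26b1 (5.37), Tll1 (4.18), Pdlim3 (3.87), Pdzd3 (2.27), Mecom (1.78) and Slc14a2 (-4.51) were still called, while Fgf15 (4.36, adjusted p = 0.088), Gabrg1 (2.92, adjusted p = 0.054) Rxrg (3.51, adjusted p = 0.17), Pdzrn3 (0.62, adjusted p = 0.77), Dio2 (-1.87, adjusted p = 0.073) and Ednrb (0.67, adjusted p = 0.45) were not. Limma called 146 genes higher and 295 lower at E15.5 (441). Without the 5 C libraries it called 28 higher and 11 lower (39), all among the 441, and without WT B and C 47 higher and 11 lower (58), which leaves 1 WT library that is assumed to vary like the other groups. On the recovered reads edgeR called 166 higher and 601 lower. Leaving out 1 library gave 168 higher and 947 lower without WT A (1115), 80 and 59 without WT B (139), and 72 and 60 without WT C (132). It gave 84 and 96 without cKO A (180), 80 and 112 without cKO B (192), and 76 and 87 without cKO C (163).

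**Figure D3:**
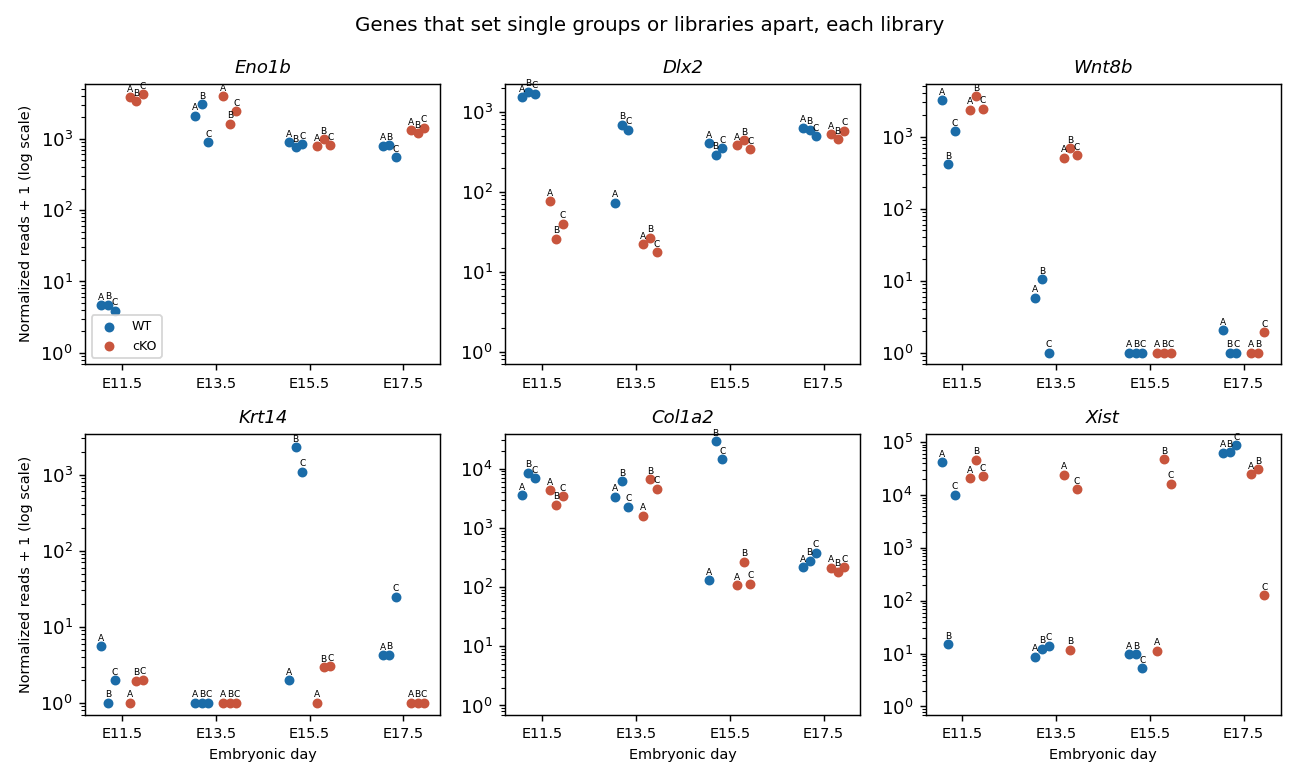
Normalized reads + 1 (y axis, log scale) of Eno1b, Dlx2, Wnt8b, Krt14, Col1a2 and Xist in each library by embryonic day (x axis), WT in blue and cKO in red, with the replicate letter beside each point. Eno1b is near 0 only in the E11.5 WT libraries, at 3.71 or less, and Krt14 and Col1a2 set WT libraries B and C apart at E15.5.

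At E17.5, where Prdm16 itself was higher under the cKO label, genes of progenitors were higher and genes of neurons lower in the libraries labelled cKO. Of 18 radial glia genes 17 rose, also adjusted over the list alone. Vim, an intermediate filament of radial glia, averaged 45800 ± 2550 against 9900 ± 1610 (2.22 ± 0.17, adjusted p = 4.2e-09), Hes5 rose by 2.18 ± 0.25 and Slc1a3 by 2.17 ± 0.15. The camera adjusted p was 1.64e-15 (adjusted p = 0.00444 with an estimated correlation). Each of the 16 S phase genes rose, led by Gins2 (1.56 ± 0.17), Mcm3 (1.51 ± 0.11) and Uhrf1 (1.47 ± 0.13), and each of the 16 G2 and M phase genes, led by Aurkb (1.56 ± 0.14), Ccnb1 (1.54 ± 0.11) and Cdk1 (1.48 ± 0.13), with the same counts adjusted over the list alone. The camera adjusted p was 3.25e-14 for S phase (adjusted p = 0.0972 with an estimated correlation) and 5.08e-14 for G2 and M phase (adjusted p = 0.0268 with an estimated correlation).

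Of 12 intermediate progenitor genes 10 rose at E17.5, also adjusted over the list alone, with Gadd45g at 2.36 ± 0.26, Neurod1 at 1.53 ± 0.09 and Eomes, the transcription factor that marks these cells, at 1.19 ± 0.10. Their camera adjusted p was 3.43e-06 (adjusted p = 0.267 with an estimated correlation). In the NOTCH pathway 9 of 13 genes rose and 2 fell (10 and 3 adjusted over the list alone), with Lfng at 2.12 ± 0.17 and Hes1 at 1.77 ± 0.19, at a camera adjusted p of 0.00451 (adjusted p = 0.453 with an estimated correlation). Of 40 antioxidant genes 16 rose and 4 fell, the same adjusted over the list alone, led by Gsta4 (2.63 ± 0.59), Gpx3 (2.28 ± 0.19) and Gpx8 (2.19 ± 0.17), at a camera adjusted p of 0.00157 (adjusted p = 0.517 with an estimated correlation).

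Of 12 deep-layer genes 11 fell in the libraries labelled cKO (12 adjusted over the list alone). Ldb2 fell from 3880 ± 442 to 874 ± 273 (-2.19 ± 0.24), Hs3st4 changed by -1.75 ± 0.46 and Foxp2 by -1.53 ± 0.27. The camera adjusted p was 2.68e-06 (adjusted p = 0.0125 with an estimated correlation). Of 14 postmitotic genes 11 fell (12 adjusted over the list alone), with the neurofilament genes Nefl and Nefm at -2.70 ± 0.25 and -2.18 ± 0.22 and Syt1, a synaptic vesicle protein, at -1.75 ± 0.21, at a camera adjusted p of 3.22e-07 (adjusted p = 0.267 with an estimated correlation). Of 10 genes of Cajal-Retzius cells, early neurons of the cortical surface, 9 fell and 1 rose, also adjusted over the list alone. Reln fell from 15100 ± 1860 to 738 ± 669 (-4.73 ± 0.42, adjusted p = 2.8e-08), Lhx5 changed by -4.88 ± 0.45 and Trp73 by -4.70 ± 0.46. Their camera adjusted p was 3.43e-06 (adjusted p = 0.0936 with an estimated correlation). Of 12 upper-layer genes 8 fell and 2 rose, also adjusted over the list alone, with Inhba at -3.36 ± 0.51 and Mef2c at -2.39 ± 0.29, at a camera adjusted p of 0.061.

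The highest fold changes at E17.5 were those of Pdlim3 (410 ± 58.4 against 1.84 ± 0.647, 7.20 ± 0.48), Fgf15 (126 ± 18.3 against 0.38 ± 0.658, 6.61 ± 0.79) and Has2, which encodes a hyaluronan synthase (474 ± 50.9 against 5.52 ± 3.95, 6.37 ± 0.95). Slc35d3 (6.04 ± 0.39), Cyp26b1 (5.32 ± 0.60), Dbx1 (5.24 ± 0.65), Tac2 (5.01 ± 0.35) and Rxrg (4.88 ± 0.62) followed. Pdzrn3, which encodes a ubiquitin ligase, averaged 14500 ± 507 and 3630 ± 345 (2 ± 0.15, adjusted p = 2.9e-09), and Ppargc1a did not pass (-0.29 ± 0.13, adjusted p = 0.083). Of 12 microglial genes 6 rose (7 adjusted over the list alone), with C1qa at 0.88 ± 0.21 and P2ry12 at 0.84 ± 0.20, at a camera adjusted p of 0.0156 (adjusted p = 0.517 with an estimated correlation). The median fold change of 12 blood vessel genes was -0.08 and of 12 meningeal genes -0.66, against 1.71 for radial glia. Of 11 erythroid genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -1.38 and a camera adjusted p of 0.0565. Leaving out the 5 C libraries left 1 upper-layer gene higher and 2 antioxidant genes lower.

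Limma called 3259 genes higher and 3822 lower at E17.5 (7081), and 5810 without the 5 C libraries, of which 5799 were among the 7081. The libraries labelled WT all held Xist without Y-linked transcripts, and cKO library C was the only 1 of the 6 with Y-linked transcripts.

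**Figure D4:**
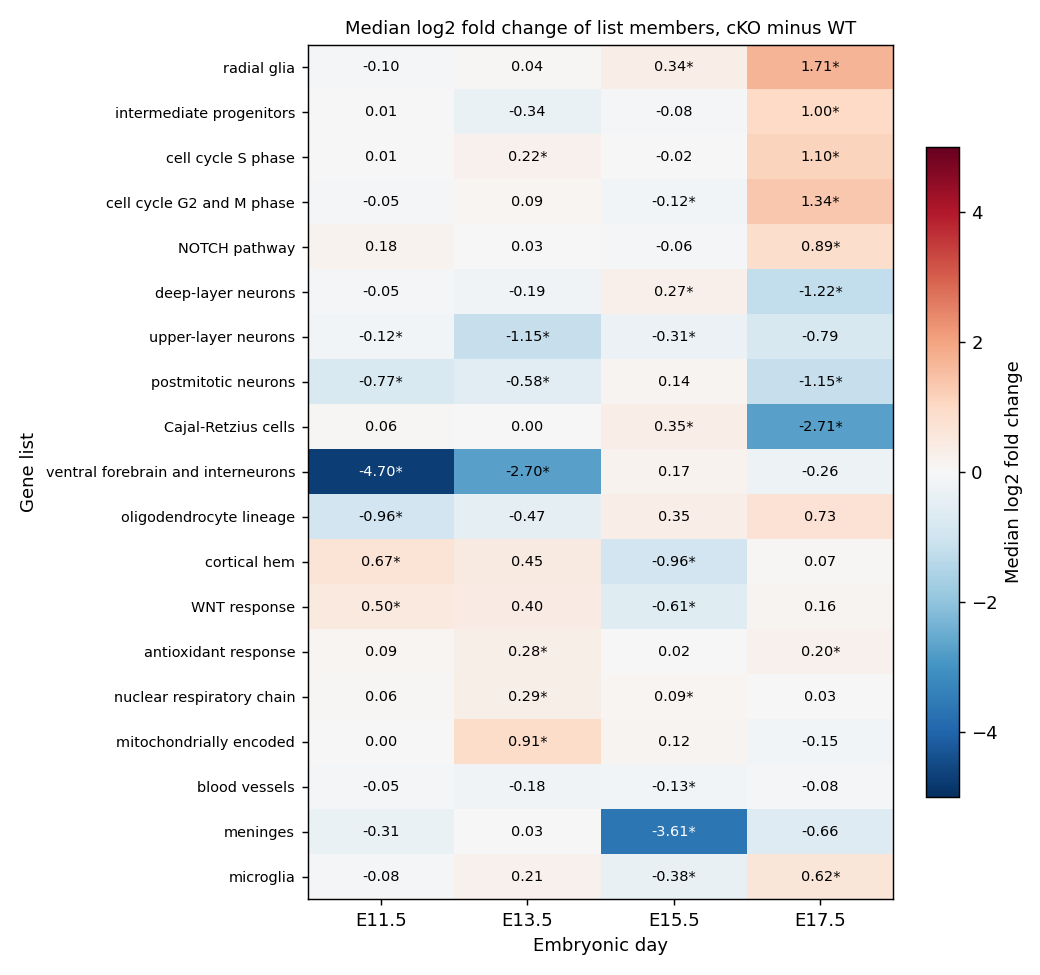
Median log2 fold change, cKO minus WT, of the members of 19 gene lists (rows) on each embryonic day (columns), on a colour scale from blue (lower in cKO) to red (higher), with an asterisk where camera's adjusted p at the preset correlation is below 0.05. Radial glia genes reach 1.71 at E17.5 and ventral forebrain genes -4.70 at E11.5.

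Averaged over the 4 days, 16 of 18 radial glia genes rose and 1 fell, also adjusted over the list alone, with Hes5 at 0.83 ± 0.13, Vim at 0.71 ± 0.09 and Fabp7 at 0.70 ± 0.11 (camera adjusted p = 6.13e-09, adjusted p = 0.0617 with an estimated correlation). By day the list medians were -0.10 at E11.5, 0.04 at E13.5, 0.34 at E15.5 and 1.71 at E17.5. At E13.5 1 of the 18 rose and 5 fell (3 and 5 adjusted over the list alone), with a mean of -0.09 against the median of 0.04 and a camera adjusted p of 0.682. On that day 2 fell without the 5 C libraries, and limma and edgeR called 0 higher, with 1 higher at an unadjusted limma p under 0.05. All 12 upper-layer genes fell, also adjusted over the list alone, with Inhba at -1.62 ± 0.26, Pou3f1 at -1.25 ± 0.11 and Rorb at -1.16 ± 0.12 (camera adjusted p = 1.97e-07, adjusted p = 0.105 with an estimated correlation). Of 14 postmitotic genes 13 fell, also adjusted over the list alone, with Mapt at -0.92 ± 0.12, Nefm at -0.89 ± 0.11 and Dcx at -0.82 ± 0.10 (camera adjusted p = 1.12e-08, adjusted p = 0.182 with an estimated correlation). The medians of that list by day were -0.77, -0.58, 0.14 and -1.15, and those of the upper-layer list -0.12, -1.15, -0.31 and -0.79. Rcan2, an inhibitor of calcineurin, rose by 1.42 ± 0.05 (adjusted p = 1.1e-13) and Pdzd3 by 2.21 ± 0.14, and these were the only 2 genes that met the conditions of the naming rule over all 12 libraries of each genotype. Pdzrn3 rose by 0.79 ± 0.07 (adjusted p = 3.1e-07), Ppargc1a changed by -0.49 ± 0.07 (adjusted p = 1.5e-05) and Prdm16 by -0.51 ± 0.07 (adjusted p = 2e-05). In all, 2833 genes were higher and 3395 lower on average (6228), and 2995 without the 5 C libraries, of which 2987 were among the 6228. The excess of lower genes shrank with TMM factors (3104 higher and 3211 lower) and turned with edgeR on the recovered reads (3140 and 3078).

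Some genes passed on several days, whose comparisons share no libraries. Higher in cKO on each of the 4 days were 10 genes, among them Gdpd2 (1.56, 1.56, 1.68 and 2.89 from E11.5 to E17.5), Optc, Rcan2, Tgif1, Hs2st1 and Nlrx1, and 3 were lower on each, Smoc1 (-1.68, -1.16, -2.63 and -0.83), Adamtsl1 and Col22a1. These were chosen after their values were seen. Gdpd2 was the only 1 still higher on 4 days without the 5 C libraries, and Smoc1 the only 1 still lower on 4. On at least 3 days 50 genes were higher and 169 lower, and without the 5 C libraries 8 and 17. Of the genes higher at E15.5 and at E17.5, 123 were shared, where independent lists would share 27.2 (Fisher's exact test, two-sided, adjusted p = 2.6e-66, across genes, which are not independent replicates). Lower genes shared 49 between these days, fewer than the 64.4 of independent lists (Fisher's exact test, two-sided, adjusted p = 0.034, across genes). Of the genes lower at E15.5, 48 were called higher at E17.5.

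The cKO effect differed between days for 5643 genes in the joint F test, 2428 without the 5 C libraries. The smallest p belonged to Eno1b, followed by Megf10 (-0.50, -0.68, 0.45 and 2.24 from E11.5 to E17.5), Jam2 (-0.18, 0.13, 0.70 and 2.02) and Ddah1 (-0.72, -0.57, 0.27 and 1.73), with SE of 0.10, 0.07 and 0.09. Sox8 went from -1.01 at E11.5 to 2.25 at E17.5 (SE 0.13) and Pxylp1 from 0.02 to 2.49 (SE 0.11). Lpl, which encodes lipoprotein lipase, stood at -0.01, 0.27, 0.42 and -1.86 (SE 0.10). Of 224 genes named in the cKO comparisons, 179 had effects that differed between days. Between adjacent days the effect differed for 50 genes from E11.5 to E13.5, 1088 from E13.5 to E15.5 and 5102 from E15.5 to E17.5, and for 7, 10 and 2673 without the 5 C libraries. From E13.5 to E15.5 the effect moved up for 750 genes and down for 338, which was 531 and 380 with TMM factors and 717 and 687 with edgeR on the recovered reads.

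The WT libraries alone give the course of the tissue over time. From E11.5 to E13.5 genes of the cortical hem fell, 8 of 13 over all genes and over the list alone, with Wnt8b from 1610 ± 1450 to 4.75 ± 4.72 (-8.22 ± 0.66), Msx2 at -6.30 ± 0.93 and Rspo1 at -6.06 ± 1.04 (camera adjusted p = 0.0114, adjusted p = 0.512 with an estimated correlation), and 5 fell without the 5 C libraries. Of 12 upper-layer genes 10 rose, also adjusted over the list alone (camera adjusted p = 7.29e-05, adjusted p = 0.485 with an estimated correlation), and 62 of 68 nuclear respiratory chain genes fell, also adjusted over the list alone (camera adjusted p = 1.44e-13, adjusted p = 0.512 with an estimated correlation). Lin28a, an RNA-binding protein of early progenitors, fell from 127 ± 51.9 to 3.15 ± 4.65, and Csmd3 rose by 5.71 ± 0.43. Prdm16 rose by 1.36 ± 0.14 (adjusted p = 5.8e-07). In all, 5185 genes rose and 4497 fell (9682), and 6793 changed without the 5 C libraries.

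From E13.5 to E15.5 in WT each of the 16 S phase and 16 G2 and M phase genes fell, also adjusted over the list alone, with list medians of -1.49 and -1.56 (camera adjusted p = 1.64e-15 and 3.73e-14, adjusted p = 0.113 and 0.0534 with an estimated correlation). Of 18 radial glia genes 14 fell and 2 rose, also adjusted over the list alone, and 1 rose without the 5 C libraries (camera adjusted p = 6.02e-08, adjusted p = 0.0534 with an estimated correlation). Robo3 fell from 2420 ± 298 to 17.3 ± 7.99 (-7.15 ± 0.32), the embryonic globin gene Hbb-y from 68900 ± 22600 to 463 ± 41.9, and Cldn11 changed by -6.92 ± 0.35. Krt14, a keratin, was listed at 0 in the WT libraries at E13.5 and read 0.977, 2301 and 1088 in A, B and C at E15.5, and Prdm16 changed by -1.08 ± 0.14. In all, 4244 genes rose and 3990 fell (8234), and 6055 changed without the 5 C libraries.

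From E15.5 to E17.5 in WT the cell cycle genes fell again, 16 of 16 in S phase and 15 of 16 in G2 and M phase (16 and 16 adjusted over the list alone), with camera adjusted p of 7.4e-10 and 5.75e-12 (adjusted p = 0.18 and 0.127 with an estimated correlation). Of 14 postmitotic genes 10 rose, also adjusted over the list alone (camera adjusted p = 1.54e-05, adjusted p = 0.327 with an estimated correlation). Tcerg1l rose from 36.1 ± 7.54 to 754 ± 184 (4.34 ± 0.32), the kinase gene Ptk2b by 4.20 ± 0.39, and Cckar fell from 52.3 ± 10.5 to 2.52 ± 3.42. Xist rose from 7.26 ± 2.56 to 72100 ± 13300 and Eif2s3y, on the Y chromosome, fell from 3610 ± 104 to 0.73 ± 1.26, so that this comparison also sets libraries of one sex against those of the other. In all, 3076 genes rose and 2549 fell (5625). The count was 2819 without the 5 C libraries, 1351 without WT E15.5 B and C, and 3696 without WT E15.5 B alone.

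Over the whole course, from E11.5 to E17.5 in WT, all 14 postmitotic genes rose, also adjusted over the list alone, with Mapt at 5.44, Myt1l at 5.26 and Neurod6 at 4.61 (camera adjusted p = 3.39e-07, adjusted p = 0.226 with an estimated correlation). Of 10 early temporal progenitor genes 9 fell, also adjusted over the list alone, with Hmga2 at -8.43, Lin28a at -6.58 and Dmrt3 at -5.26 (camera adjusted p = 8.67e-05, adjusted p = 0.226 with an estimated correlation). Of 12 late temporal progenitor genes 10 rose and 2 fell, also adjusted over the list alone, with Slco1c1 at 7.37, Tnc at 6.46 and Nfix at 5.07 (camera adjusted p = 0.0125, adjusted p = 0.362 with an estimated correlation). The embryonic globin genes Hbb-bh1 (-13.15 ± 0.67) and Hbb-y (-12.32 ± 0.30) had the lowest fold changes, and Inhba (9.01 ± 0.51), the glutamate receptor genes Grm5 (8.78 ± 0.70) and Grin2b (8.67 ± 0.57), and Nos1 (8.52 ± 0.47) were among the highest. In all, 6731 genes rose and 6382 fell (13113), and 11645 changed without the 5 C libraries, of which 11621 were among the 13113.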

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

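All tests of the 3 patterns weighed here were chosen after the result was seen, except that of reads of Eno1 counted for its copies, while the test of the effects between days and the splits of all 24 libraries were chosen before. Splits without the 5 C libraries were added after seeing the data, since splits count each library as a separate sample. The cKO effect differed between days for 5643 genes in the joint F test, which drew attention because a difference between days was itself tested. In 4 of 100 drawn splits of the libraries the F test gave as many genes, the real split included, and the highest other gave 10057. A split that swaps the genotypes on a single day turns an effect shared by all days into a difference between days. The splits therefore cannot decide whether the effect differs between days, and what lies behind the 10057 was not tested. The F test gave 2428 genes without the 5 C libraries and 5 of 100 splits gave as many (highest other 4328), so the share of splits was under 0.05 over all libraries but not over this set. Between adjacent days the effect differed for 50 genes from E11.5 to E13.5, and chance cannot be excluded there (8 of 100 splits, highest other 6384). With the 5 C libraries left out, the count there was 7 (19 of 100 splits, highest other 1544). The effect differed for 1088 genes from E13.5 to E15.5 (2 of 100 splits, highest other 1859), 10 without the 5 C libraries (3 of 100 splits, highest other 30) and 28 without WT E15.5 B and C. From E15.5 to E17.5 it differed for 5102 genes (2 of 100 splits, highest other 5282), and for 2673 without the 5 C libraries (2 of 100 splits, highest other 3274). On both sets of libraries the share of splits was under 0.05 for these last 2 steps, which does not exclude chance for a difference between days.

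Single genes drew attention by the same test, each with its fold changes from E11.5 to E17.5. Eno1b stood at 9.73, 0.47, 0.04 and 0.88 (limma F test, adjusted p = 3.2e-11). Megf10 stood at -0.50, -0.68, 0.45 and 2.24 (6.7e-11). Jam2 stood at -0.18, 0.13, 0.70 and 2.02 (7.7e-11). Ddah1 stood at -0.72, -0.57, 0.27 and 1.73 (6e-10). Sox8 stood at -1.01, -0.67, 0.57 and 2.25 (9.5e-10). Pxylp1 stood at 0.02, 0.07, 1.5 and 2.49 (2.3e-09). Lpl stood at -0.01, 0.27, 0.42 and -1.86 (3.1e-09). Ppargc1a stood at -0.50, -0.97, -0.18 and -0.29 (0.0093, and 0.092 without the 5 C libraries). Pdzrn3 stood at -0.03, 0.54, 0.66 and 2 (3.5e-06). Prdm16 stood at -1.06, -1.56, -0.18 and 0.76 (2.5e-07). Groups of 3 libraries were not tested for outliers.

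Library C lies between A and B in 5 groups, and if it were not a separate sample the p-values above would be too small. If each C library were a single embryo, its Y-linked transcripts would be near 0% or near 100% of the level in the Y-carrying library of its group, and the lowest was 51.9%, which argues against it. If C held RNA of both A and B, the share of the Y-carrying library would be the same from Y-linked genes as from other genes within 10 percentage points, a bound met at WT E11.5 (69.8% and 67.9%) and cKO E13.5 (51.9% and 53.4%) but missed by cKO E15.5 (71.3% and 82.3%), a largest difference of 11 points. A simple sum therefore failed its own bound in 1 of 3 groups, and other ways for RNA to be shared, as well as sampling of tissue from more than 1 embryo, may remain open and were not tested. A split of the E11.5 libraries set cKO A, cKO C and WT B against cKO B, WT A and WT C. It called 2663 genes, several times the real 548, which points to a structure of the samples. On the first principal component cKO B scored -111.53, among the WT libraries (-112.42 to -109.28), against -138.32 and -135.76 for cKO A and C. At E13.5 cKO B scored -45.05, nearer to WT (-41.96 to -3.52) than cKO A (-93.26) and cKO C (-66.42). Prdm16 was still lower in both of these B libraries than in each WT library of the same day.

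Eno1b, the predicted genes Gm5855 and Gm13225, and Masp2 are near 0 in the E11.5 WT libraries alone, and loss of Prdm16 as the cause is argued against by the WT libraries of the other days, where Eno1b is at least 553. Genes within 10 Mb of Prdm16 were called at E11.5 more often than others, 23 of 167 against 525 of 17351 (odds ratio 5.12, 95% interval 3.12 to 8.07, Fisher's exact test, two-sided, adjusted p = 3e-08, across genes, which are not independent replicates), with odds ratios of 0.922, 0.706 and 0.963 on the later days. The excess depends on the window, with odds ratios of 2.93 within 5 Mb (interval 1.36 to 5.64) and 2.98 within 20 Mb (1.88 to 4.54), and without the 5 C libraries limma and edgeR each called 0 of 117, 6 of 167 and 7 of 293 genes within 5, 10 and 20 Mb (14, 32 and 36 at an unadjusted limma p under 0.05). Of the genes outside these windows limma then called 97 of 17401, 91 of 17351 and 90 of 17225. The share called thus stayed higher near Prdm16 within 10 and 20 Mb but not within 5 Mb. A candidate explanation is another parental chromosome around Prdm16 in those WT libraries, and Eno1b followed Eno1 over the other 21 libraries (ratio of SDs 0.303), so reads of Eno1 that match a copy held by only some chromosomes may contribute. Strain differences were not tested, since the labels name 1 strain.

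Progenitor genes are higher and neuron genes lower in the libraries labelled cKO at E17.5, where Prdm16 is higher too. Of the genes called higher in cKO at E15.5, 134 of 146 had a positive fold change at E17.5 (91.8%, exact 95% interval 86.1 to 95.7, across genes). The 295 genes lower at E15.5 do not decide, since 49 were lower and 48 higher at E17.5. The 49 are fewer than the 64.4 of independent lists (Fisher's exact test, two-sided, adjusted p = 0.034, across genes). Prdm16 did not differ at E15.5. Swapped genotype labels at E17.5 are also argued against by E13.5, where Prdm16 fell, since 688 of 1715 higher genes were higher again and 114 lower, and 1125 of 2196 lower genes were lower again and 157 higher (319 and 479 for independent lists). On these 2 days alone the names of the WT columns carry a 2 of unknown meaning, so genotype cannot be told apart from whatever it marks. A difference that it brought would also be shared by both days. A lower share of neurons that raises every other cell type alike is argued against by the median fold changes of radial glia and blood vessel genes, 1.71 and -0.08, which differ by 1.79 (permutation test, two-sided, p = 3e-05, across genes). A higher share of radial glia may account for the rise of Prdm16, since 17 of 18 radial glia genes rose by more than its 0.76, and whether such a share comes from the genotype or from how the tissue was taken was not tested.

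For the other counts the splits were these. The average over days gave 6228 genes, 1 of 100 splits gave as many and the highest other gave 2741. Leaving out the 5 C libraries, these were 2995, 1 of 100 and 2068. The share of splits was thus under 0.05 on both sets. Splits count each library as a separate sample, which is in doubt here, so chance is not excluded. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 548 and 2663 at E11.5 (2 splits as large), 3911 and 294 at E13.5, 441 and 33 at E15.5, and 7081 and 1 at E17.5. In WT they were 9682 and 4 from E11.5 to E13.5, 8234 and 173 from E13.5 to E15.5, 5625 and 128 from E15.5 to E17.5, and 13113 and 1 from E11.5 to E17.5.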

How the results depend on the processing

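The alternatives without the 5 C libraries and without WT E15.5 B and C were chosen after seeing the data. Of 803 named values, 797 had been called in the main fit, which makes a reversal unlikely. None reversed with TMM factors, either pseudocount or edgeR. Dropping the trend or adding the replicate block leaves the fold changes as they are, so none could reverse there. The number no longer past the threshold was 5 with TMM, 23 with edgeR, 40 without the trend and 50 with the block. It was 226 without the 5 C libraries. It was also 2 to 20 under the other filters and pseudocounts, 222 with edgeR without the 5 C libraries, and 135 of 709 with only the 2 groups compared. Without WT E15.5 B and C, a setting run on only part of the 803 values, 8 reversed and more were no longer past the threshold. Leaving out each library in turn, with a named value counted once for each omission tested, 733 results were no longer past the threshold and 5777 stayed. Limma without the trend called 690 genes for the effect at E15.5 minus E13.5, and edgeR on the recovered reads called 767 at E15.5. With only the 2 groups compared, which leaves fewer libraries to estimate the spread, 138 genes were called at E11.5 and 640 at E13.5. An absolute log2 fold change of at least 1, a stricter rule by construction, left 278 genes at E11.5, 745 at E13.5, 2703 at E17.5 and 446 on average, 3071, 3188, 1532 and 7559 along the WT course (E11.5 to E13.5, to E15.5, to E17.5 and E11.5 to E17.5), and 33, 547 and 2612 for the effects between adjacent days. Without the 5 C libraries, which are fewer samples, limma called 97, 462 and 39 genes at E11.5, E13.5 and E15.5, 2995 on average, 2819 for WT E17.5 minus E15.5, 7, 10 and 2673 for the effects between adjacent days and 2428 in the F test. With edgeR these were 80, 332, 40, 2911, 3132, 6, 8, 2824 and 2416. Without WT E15.5 B and C, 58 genes were called at E15.5, 1351 for WT E17.5 minus E15.5, and 28 and 2541 for the effects at E15.5 minus E13.5 and E17.5 minus E15.5. Fold changes reversed there for Col1a2 (0.19) and Col3a1 (0.49) at E15.5, for Pmel (-0.039) in WT E15.5 minus E13.5, and for Col3a1 (0.48), Twist1 (0.26), Col1a1 (2.02), Pmel (0.25) and Klf4 (0.19) in WT E17.5 minus E15.5. Where the construction does not show it, the cause was not tested.

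The letters were checked as a pairing. Over 12 pairs of same-lettered WT and cKO libraries the correlation of deviations from the group means, across genes, ran from -0.428 to 0.11, with 1 over 0.1, and 4 libraries were closest to their own letter, so the letters were not taken to pair the samples. With the letter as a replicate block 2265 genes were called at E13.5, 271 at E15.5, and 20 and 408 for the effects at E13.5 minus E11.5 and E15.5 minus E13.5.

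For gene lists, camera at the preset correlation called 9, 8, 15 and 11 lists from E11.5 to E17.5, 12 on average, and 13, 14, 13 and 19 along the WT course. Without the 5 C libraries it called as many in each cKO comparison and 11, 15, 12 and 19 along the WT course. With a correlation estimated from the data it called 2 at E11.5 (ventral forebrain, oligodendrocyte lineage), 0 at E13.5, 0 at E15.5, 3 at E17.5 (radial glia, deep-layer neurons, G2 and M phase), 0 on average and 0 in each WT comparison. Fry, which does not compare a list with other genes, called 4, 7, 0 and 20 lists from E11.5 to E17.5, 18 on average, and 23, 23, 17 and 31 along the WT course.

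Leaving out 1 library gave 270 (without WT B) to 1436 (without cKO B) genes at E11.5, 1539 (cKO A) to 5888 (cKO B) at E13.5, 132 (WT C) to 1115 (WT A) at E15.5, 5598 to 6860 at E17.5, 5266 to 7784 on average, 8041 to 9613, 6962 to 7941, 3696 (WT E15.5 B) to 5752 and 12308 to 12854 along the WT course, and 4649 to 6873 in the F test. The effect at E13.5 minus E11.5 ranged from 21 (WT E11.5 C) to 627 (cKO E13.5 B), with 286 without WT E11.5 A, 32 without WT E11.5 B, 78 without cKO E11.5 A, 32 without cKO E11.5 C, 83 without WT E13.5 B and 29 without cKO E13.5 C. At E15.5 minus E13.5 it ranged from 243 (WT E13.5 C) to 2510 (cKO E13.5 B), with 600 and 362 without cKO E13.5 A and C, 1834, 266 and 351 without WT E15.5 A, B and C, and 252 and 262 without cKO E15.5 A and C. At E17.5 minus E15.5 it ranged from 4046 to 5467. Depth limits the genes near the filter's minimum of 10, and in simulated data 41.8% of the 67 genes changed 1.5-fold at E11.5 were recovered.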

Other observations

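Etv4 and Etv5, transcription factor genes that respond to FGF signalling, rose at E17.5 in the libraries labelled cKO by 2.33 ± 0.27 and 1.27 ± 0.27 (SE, n = 3), and Emx2 by 1.34 ± 0.19, in a list of 11 area and dorsal patterning genes of which 4 rose, also adjusted over the list alone (camera adjusted p = 0.125). Psat1 and Phgdh, enzymes of serine synthesis, rose by 1.82 ± 0.10 and 1.41 ± 0.14, and Vldlr, a receptor for reelin, changed by -1.34 ± 0.17, in an integrated stress response list of 12 of which 3 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.641). Among relatives of Prdm16, Prdm12 averaged 43.6 ± 5.65 and 4.02 ± 1.15 (3.17 ± 0.29), in a list of 10 PRDM family genes of which 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.707; list median -0.25, mean 0.27).

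Glial genes moved apart at E17.5. Tnc and Aldoc rose by 1.96 ± 0.77 and 1.74 ± 0.29, and Gfap fell from 51.4 ± 8.99 to 9.76 ± 3.36 (-2.32 ± 0.50), in an astrocyte list of 12 of which 3 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.129). Mbp, a myelin protein gene, fell from 908 ± 47.8 to 354 ± 29.9, in an oligodendrocyte list of 10 of which 3 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.311, list median 0.73). Leaving out the 5 C libraries, 1 astrocyte gene fell. Dct, which encodes a melanin enzyme, rose from 134 ± 46.9 to 1320 ± 498 and Tcf7l2 from 166 ± 15.2 to 576 ± 27.3, 2 of 7 genes of eye and diencephalon, also adjusted over the list alone (camera adjusted p = 0.129).

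The tests that follow were chosen before the result was seen, except the settings said to be added. One hypothesis is that cKO tissue may be like WT tissue of an earlier day, so that the cKO change runs against the WT course measured in libraries of other days. Across genes, which are not independent replicates, Spearman's rho between them was -0.23 at E11.5, -0.60 at E13.5 and -0.55 at E17.5, below the bound of -0.1 set for it, and 0.19 at E15.5. Of the genes called, 73.2%, 91.7% and 84.3% went against the WT course on those 3 days and 41.3% at E15.5. At E15.5 rho missed the bound, so the prediction failed on that day. In settings added after seeing the data, rho at E15.5 was 0.14 without the 5 C libraries and -0.07 without WT E15.5 B and C. These values miss the bound as well. Without the 5 C libraries 71.8% of the calls went against the course. A rule added after these values were seen gives no verdict where rho changes its sign, and by it that day was left undecided. On the other days rho was -0.23 at E11.5 without the 5 C libraries, -0.59 and -0.58 at E13.5 in the 2 settings, and -0.54 in both at E17.5. Pearson's r was -0.15, -0.53, 0.17 and -0.47 from E11.5 to E17.5.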
